A study of Drosophila melanogaster with 3 samples.

How the data were processed

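The assay was ChIP-seq with an antibody against GFP on chromatin of whole Drosophila melanogaster embryos aged 0 to 24 h that express CG2116 with eGFP at its C terminus. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. All 3 libraries belong to 1 group, and the replicate numbers 1, 2 and 4 are those of the labels. Nothing beyond these numbers describes separate collections of embryos, so the spread between replicates may be in part technical. With a single group there is no comparison between conditions, and no outlier test was run on 3 values.

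The authors deposited, for each of the genome builds dm6 and dm3, 3 replicate peak lists described as peaks and background for the IDR procedure, 1 relaxed list from pooled replicates and 1 optimal IDR list, 5 lists per build. Peaks were thus called by the authors both per replicate and on pooled replicates. Per the deposited description of the files, each list was made from the alignments named there and 1 further file of unstated kind, taken here to be the control. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The deposited signal of each peak is the caller's enrichment value, whose scale depends on the caller and the depth; it was used only to rank peaks within a list or after division by the list's median. The deposited −log10 q of each peak was not used in a test, since 91.9% of the IDR peaks shared its maximum of 4.12. Depth per library is not given in the files used here, so the precision it allows is unknown. Read-level signal tracks and a control library were not analysed here.

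Each IDR peak was found in the pooled relaxed list with the same interval and summit. The background for the IDR peaks was the 21020 pooled peaks that overlapped none of them by 1 bp or more. No pooled peak in this background had a higher signal than the weakest IDR peak, at 144.1. Coordinates are 1-based on dm6. Genes and TSSs came from Ensembl release 115 and sequence from the RefSeq copy of the same assembly, on arms 2L, 2R, 3L, 3R, 4 and X. The dm3 lists were used for counts only.

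An IDR peak counted as recovered in a replicate when one of that replicate's 7137 strongest summits lay within 100 bp, and the strongest 7137 summits of each replicate were compared with those of each other one in the same way, with chance from 100 random draws of as many peaks from the other's whole list. Relative signal is the signal of the nearest replicate summit within 100 bp divided by that replicate's median over such peaks, 77.8, 99.0 and 132.8 in replicates 1, 2 and 4. A summit within 500 bp of the TSS of a protein-coding gene was a promoter summit. Other summits were classed in the order 5' untranslated region, 3' untranslated region, coding exon, other exon, intron and intergenic. A gene was bound when an IDR summit lay within 500 bp of any of its TSSs. Each of 22 gene lists was compared with the other protein-coding genes. Each of 15 motifs was searched on both strands within 100 bp of the summit, and all 6-mers and 8-mers were tested on 2L, 2R and 4 and retested on 3L, 3R and X. All tests were two-sided Fisher's exact tests with Benjamini-Hochberg adjustment at 0.05 within each family, except the retest of k-mers, which used a Bonferroni correction, the promoter share, a single Fisher's exact test, and the sides of TATCGATA, an unadjusted exact binomial test. Odds ratios have Woolf 95% intervals, with 0.5 added where a count was 0, and shares have exact Clopper-Pearson intervals. An exact adjusted p is Fisher's exact p after that adjustment. Intervals cover counting error only, and peaks and genes are not independent replicates. A p-value under 1e-300 was written as that bound.

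The lists, motifs, tests and most alternatives were fixed before the data were examined, as was the rule for the items named: the 25 strongest promoter peaks, the 5 strongest other peaks, the 4 strongest bound members of each gene list that passed or had at least 3 bound members, the insulator protein list and CG2116. After that, 4 gene symbols were updated to the names in the annotation. Alternatives changed the match distance, the promoter and motif windows, the peak set, the background and the replicates used. In the promoter, feature, arm, gene list, motif and k-mer tests, dropping a replicate meant keeping the IDR peaks recovered in both others. The IDR list, the pooled signal and the background still came from all 3 libraries. These runs are thus a stricter peak filter and do not show independence from a replicate. Comparing the strongest summits of pairs of replicates, comparing feature classes among summits outside promoters, dropping each replicate from the feature, arm, gene list, motif and k-mer tests, dropping IDR peaks beside a stronger summit, and everything on GCAACNCT, on sets by strength, on positions of elements around summits and on gene starts over 1000 bp from other genes was added after seeing the data.

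The code was checked on simulated data made from the same lists. A simulated replicate that kept 89.3% of 7137 IDR peaks gave 89.3% recovered. Its kept summits moved by less than the match distance and were made its strongest, so this outcome was close to fixed. It checks the code and not the noise of real replicates. A planted 8-mer ranked 1, 0 8-mers sharing no 5 bases with it were called, and 0 were called with nothing planted. The planted gene list was called and 0 of 20 random ones were. The number of shuffles was raised to 1000 after a first run with fewer. Over 1000 shuffles of the IDR and lower-ranked labels the promoter odds ratio averaged 0.998, with 54 at p under 0.05. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.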

Results

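Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the product of CG2116 sits on the genome of Drosophila melanogaster. CG2116 is an X-linked gene whose product RefSeq lists as uncharacterised. The animals were whole embryos of mixed sex, 0 to 24 h old, from a line that carries CG2116 with eGFP fused to its C terminus, and the immunoprecipitation used an antibody against GFP. There was 1 group of 3 libraries, which the labels number as biological replicates 1, 2 and 4. On the dm6 build each library has a relaxed list of 30000 candidate peaks, with a median width of 530 bp in replicate 1, 600 bp in replicate 2 and 444 bp in replicate 4. A pooled relaxed list also holds 30000 peaks, and the list that passed the irreproducible discovery rate (IDR) filter holds 7137 peaks with a median pooled signal of 297 and a maximum of 33201. Sequencing depth per library is unknown here. The signal is the peak caller's own value, so strength in a replicate is given as signal divided by that replicate's median over the IDR peaks it matched.

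The 3 embryo libraries shared many of their strongest sites. The peak at the start of Rho1, a small GTPase of the actin cytoskeleton, was the strongest of the IDR list, at 106.9 ± 17.2 times the replicate median (SD, n = 3). The peak at gro, which encodes the Groucho corepressor, stood at 70.3 ± 4.38. Of the 7137 IDR peaks, replicate 1 held 84.7% among its own 7137 strongest summits within 100 bp, replicate 2 held 79.5% and replicate 4 held 86.5%, a mean of 83.5% ± 3.62 (SD, n = 3). All 3 replicates held 4604 of them, or 64.5% (exact 95% interval 63.4 to 65.6), and 34.3% with the 3568 strongest summits of each replicate. The IDR list was made from these same libraries and selects peaks that agree between replicates, so this recovery is in part built in. Without the IDR list, 70.5% to 77.1% of the 7137 strongest summits of a replicate lay within 100 bp of one of the 7137 strongest of another, a mean of 74.4% over the 6 ordered pairs against 20.98% for random draws of 7137 peaks from the other's list, a comparison added after the data were seen. The share of IDR peaks held by all 3 replicates fell with strength, from 97.2% of the 1785 strongest IDR peaks to 10.5% of the 1784 weakest. That fall depends on the cut at the 7137 strongest summits, since the whole lists of replicates 1, 2 and 4 had a summit within 100 bp of 95.7%, 94.3% and 95.4% of the IDR peaks. Across matched IDR peaks, which are not independent replicates, Spearman's rho of the signal was 0.847 between replicates 1 and 2, 0.829 between 1 and 4 and 0.746 between 2 and 4.

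Some IDR peaks lay close beside a stronger one, a count made after the data were seen. A stronger pooled summit lay within 400 bp at lower coordinates for 900 of the 7137 IDR peaks, and at higher coordinates for 30. The gap to the nearest such summit on the lower side had a median of 204 bp (quartiles 201 to 211). Without the 926 peaks that had a stronger neighbour on either side, all 3 replicates held 68.9% of the remaining IDR peaks.

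CG2116-eGFP peaks lay at gene starts. The summit of 5166 of the 7137 IDR peaks, 72.4%, was within 500 bp of the transcription start site (TSS) of a protein-coding gene, against 3972 of the 21020 lower-ranked pooled peaks, 18.9%. The odds ratio was 11.2 (95% interval 10.6 to 11.97, Fisher's exact test, two-sided, p below 1e-300). It was 8.66 with a promoter window of 1000 bp and 10.03 without IDR peaks beside a stronger summit. Among IDR peaks recovered in both of the others when 1 replicate was left out it was 13.25 to 17.1. With the 3568 strongest IDR peaks it was 24.6, and against random positions 20.7. The promoter summits lay just upstream of the TSS, at a median of -61 bp along the gene (quartiles -131 and -19), with 82.7% upstream and 61.8% within 100 bp of it. Introns held 17.4% of all IDR summits and 46.4% of lower-ranked ones, intergenic sequence 7.75% and 22.9%, coding exons 0.224% and 5.44%, 3' untranslated regions 0.743% and 3.26%, other exons 1.02% and 2.18%, and 5' untranslated regions outside the promoter window 0.462% and 0.966%. All 7 classes passed (largest adjusted p 2.33e-05, Fisher's exact test, Benjamini-Hochberg over 7 classes), but they are shares of 1 total that fall together as the promoter share rises, so these tests do not bear on single classes outside promoters. Among the 1971 IDR and 17048 lower-ranked summits outside promoters, a comparison added after the data were seen, coding exons held fewer IDR summits, 16 or 0.812% against 6.71% (odds ratio 0.114, 0.0693 to 0.187, exact adjusted p = 1.67e-35 over 6 classes). Their odds ratio was 0.186 with the 3568 strongest IDR peaks and 0.0463 against random positions. Introns held more, 63.1% against 57.2% (1.28, 1.16 to 1.41, exact adjusted p = 1.81e-06), a call lost with the 3568 strongest IDR peaks (1.02, adjusted p = 0.859), and their odds ratio was 2.10 against random positions. These 6 classes are again shares of 1 total. The higher share of introns may therefore follow from the lower share of coding exons, and introns were not tested apart from these. The calls on 3' untranslated regions (0.660, exact adjusted p = 0.00610) and other exons (1.39, adjusted p = 0.0171) were lost whichever replicate was left out (0.749 to 0.862 and 1.165 to 1.25), with the 3568 strongest IDR peaks and with those recovered in all 3 replicates. For 5' untranslated regions (1.41, exact adjusted p = 0.101) and intergenic sequence (0.994, adjusted p = 0.916) the threshold was missed and the direction depended on the setting. Against random positions both passed (1.66, exact adjusted p = 0.0113, and 0.856, adjusted p = 0.00356), and intergenic sequence did with the 3568 strongest IDR peaks (1.27, adjusted p = 0.0328). No lower-ranked peak had a higher pooled signal than the weakest IDR peak, so each comparison between these sets is one between stronger and weaker calls of the same pooled list. No list from an untagged line or an input library was used here, so sites that any anti-GFP ChIP would give were not separated from those of CG2116.

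All 25 of the strongest promoter peaks were recovered in every replicate, and 11 of them also lay within 500 bp of the TSS of another gene. After Rho1 (2R, 16102155 to 16103217, summit at -18 bp from the TSS) came E(bx), which encodes a subunit of the NURF chromatin remodeller (3L, 246513 to 247534), at 73.1 ± 11.8 times the replicate median. Next were gro (3R, 26041224 to 26042988), bchs, an autophagy adaptor (2L, 5906605 to 5907764), at 68.2 ± 9.70, and the translation initiation factor eIF2A (3L, 21824444 to 21825293) at 67.8 ± 8.19. The start shared by CG1074 and eIF3a (3R, 4433484 to 4434464) stood at 67.8 ± 6.50, and the chaperone gene Calr at 63.8 ± 12.01. GlcAT-S stood at 64.4 ± 7.60, the citron kinase gene sti at 59.2 ± 7.15, MEP-1 at 56.7 ± 4.20 and the kinesin gene Klp67A at 54.8 ± 7.93. Also among the 25 were Polr2F, a subunit of RNA polymerase II, RpL7, Cbl, CG1354, NaCP60E, whose peak also covers the start of RpL41, alc, CG34250, RpL13A, RpLP2, emb, MESR4, Doa, Fmr1 and Sry-delta, at means from 45.9 to 51.9. The coefficient of variation between replicates had a median of 11.8% over the 25 peaks and a maximum of 20.5%, so ranks among peaks with close means are not resolved. These peaks held 9.65% of the summed pooled signal of the IDR list.

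**Figure D1:**
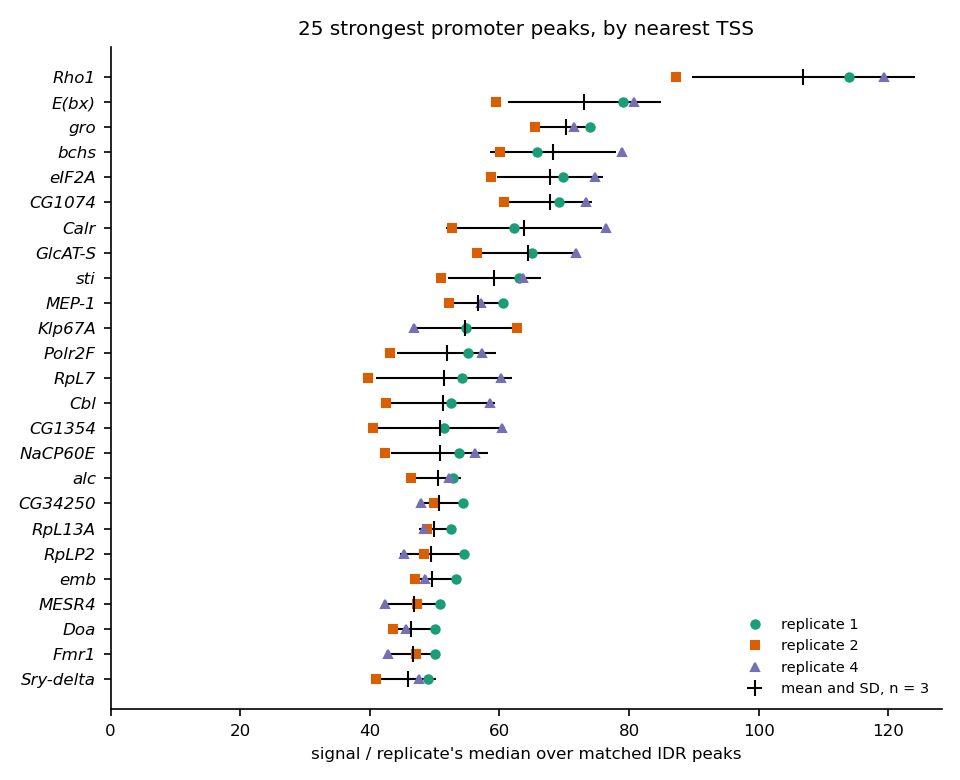
The 25 strongest promoter peaks of CG2116-eGFP, named by the nearest TSS. The horizontal axis is the signal divided by the replicate's median over the IDR peaks it matched (no unit), coloured symbols are replicates 1, 2 and 4, and black bars are the mean ± SD (n = 3). Rho1 at 106.9 stands apart from the others, which run from 45.9 to 73.1.

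The strongest site away from annotated protein-coding starts was an intergenic peak upstream of SIFaR, a neuropeptide receptor gene, with its summit at -2066 bp from the TSS (3R, 21295515 to 21296829), at 47.7 ± 6.397 times the replicate median (SD, n = 3). An intergenic peak at -504 bp from the TSS of CG3505 (3R, 14656376 to 14657385) stood at 45.3 ± 4.32. The other 3 of the 5 strongest were an intergenic peak near Sox102F on chromosome 4 (834598 to 835738) at 28.1 ± 1.66, followed by an intronic peak near COX7AL2 (2L, 2193147 to 2193885) at 25.3 ± 4.75 and a peak in a 3' untranslated region near CG5157 (3L, 16138980 to 16139639) at 22.4 ± 1.59.

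The density of sites was similar on the large arms. IDR peaks per Mb were 55.8 on 2L, 55.2 on 2R, 50.3 on 3L, 51.7 on 3R, 42.3 on 4 and 55.3 on X. Relative to lower-ranked peaks, 2R held slightly more (odds ratio 1.11, 1.04 to 1.19, adjusted p = 0.00887) and 3L fewer (0.853, 0.798 to 0.911, adjusted p = 1.46e-05), and X missed the threshold (1.08, 1.01 to 1.16, adjusted p = 0.0548; Fisher's exact test, Benjamini-Hochberg over 6 arms). The call on 2R was lost at a similar odds ratio and with fewer peaks without replicate 1 (1.095, exact adjusted p = 0.0740), with the 3568 strongest IDR peaks (1.106, adjusted p = 0.0872) and with those recovered in all 3 replicates (1.097, adjusted p = 0.0806), and X passed without replicate 4 (1.10, exact adjusted p = 0.0420). With arm length as the background neither 2R (1.04, exact adjusted p = 0.223) nor 3L (0.930, exact adjusted p = 0.199) passed.

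Genes of the translation machinery were bound far more often than other genes. Of all 13945 protein-coding genes on the 6 arms, 5941 had an IDR summit within 500 bp of a TSS, or 42.6%. Among cytosolic ribosomal protein genes 81 of 86 did, 94.2% (exact 95% interval 87.0 to 98.1), with an odds ratio of 22.1 (8.96 to 54.6) and an adjusted p of 9.05e-24 (Fisher's exact test, Benjamini-Hochberg over 22 lists). The strongest were RpL7 at 51.4 ± 10.5 times the replicate median (SD, n = 3), RpL41 at 50.8 ± 7.43, RpL13A at 49.9 ± 2.32 and RpLP2 at 49.4 ± 4.70. Their bound members had a median pooled signal of 780.4, with each gene given its strongest summit. The median was 370.9 for mitochondrial ribosomal protein genes and 572.5 for translation factors. It was 818.7 for heat shock and cognate chaperone genes, a list that missed the threshold, so a high median is not particular to ribosomal protein genes. The 297 of all IDR peaks also covers peaks outside promoters and is not a like measure. Mitochondrial ribosomal protein genes were bound at 62 of 73 (odds ratio 7.66, exact adjusted p = 6.34e-13). They were led by mRpS17 at 32.7 ± 7.85, mRpL53 at 28.1 ± 4.48, mRpS30 at 16.0 ± 1.22 and mRpS21 at 6.68 ± 0.682. Translation factors were bound at 37 of 52 (odds ratio 3.34, exact adjusted p = 1.48e-04). Behind eIF2A were eIF3a at 67.8 ± 6.50, eIF1 at 44.0 ± 4.40 and eIF4E1 at 20.3 ± 1.47. Among genes with any pooled peak at the promoter, the ribosomal lists still passed (17.1, 4.21 to 69.7, and 2.89, 1.44 to 5.83), and translation factors did not (2.58, 1.09 to 6.13, exact adjusted p = 0.0509). Many of these genes share a start region with a neighbour, so genes whose TSSs lay over 1000 bp from those of every other gene were tested alone, a choice made after the data were seen. Of 30 cytosolic ribosomal protein genes 27 were bound, with an odds ratio of 27.7 (8.40 to 91.4), and of 24 translation factors 14 were (4.28, 1.90 to 9.64). Mitochondrial ribosomal protein genes, bound at 7 of 13, missed the threshold (3.55, 1.19 to 10.6, exact adjusted p = 0.0511). When 1 replicate was left out, which keeps the IDR peaks recovered in both others, the odds ratio was 11.75 to 13.5 for cytosolic and 3.87 to 4.54 for mitochondrial ribosomal protein genes. With each cluster of genes whose starts lay within 1000 bp of each other as 1 unit, bound if any of its genes was, it was 47.5 and 12.1, with the 3568 strongest IDR peaks 12.5 and 2.77, and with those recovered in all 3 replicates 11.65 and 3.83. With a promoter window of 1000 bp it was 33.4 for the cytosolic ones. A cluster can be bound through a gene outside the list, so the odds ratios of clusters do not settle the question of shared starts.

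Genes of energy metabolism, protein turnover and the cell cycle were also bound more often. Replication and cell cycle genes were bound at 28 of 31 (odds ratio 12.6, 3.84 to 41.6, exact adjusted p = 2.57e-07). They were led by the replication licensing gene dup at 36.2 ± 8.52, CycB3 at 32.5 ± 5.36, Mcm2 at 9.26 ± 2.33 and Cdk4 at 8.32 ± 0.647 times the replicate median (SD, n = 3). Oxidative phosphorylation genes were bound at 49 of 80 (odds ratio 2.14, exact adjusted p = 0.00178). The strongest were UQCR-14 at 25.8 ± 3.24, ND-B8 at 14.8 ± 1.69, ATPsynO at 13.02 ± 1.49 and ND-ASHI at 10.3 ± 0.838. Proteasome genes were bound at 29 of 48 (odds ratio 2.06, exact adjusted p = 0.0252). The strongest were Rpn11 at 24.1 ± 5.46, Rpn2 at 4.65 ± 0.245, Prosbeta1 at 4.46 ± 0.932 and Rpn6 at 3.58 ± 0.0386. Against genes with any pooled peak at the promoter, oxidative phosphorylation (odds ratio 1.28, exact adjusted p = 0.582) and proteasome genes (3.04, adjusted p = 0.0514) did not pass, and replication and cell cycle genes did (3.91, adjusted p = 0.0323). The odds ratio of the latter was 5.06 to 5.85 when 1 replicate was left out, 5.88 with the 3568 strongest IDR peaks and 4.57 with those recovered in all 3 replicates. Proteasome genes also missed the threshold with a promoter window of 1000 bp (1.82, exact adjusted p = 0.0550) and without replicate 1 (1.76, adjusted p = 0.0710). Among genes with starts over 1000 bp from others, proteasome genes were bound at 9 of 22 and missed the threshold (2.11, exact adjusted p = 0.144), while oxidative phosphorylation (2.51, adjusted p = 0.0308) and replication and cell cycle genes (36.7, adjusted p = 3.48e-06) passed. With clusters of starts as units, 56 of 79 clusters with oxidative phosphorylation genes were bound (odds ratio 4.14). Neighbours outside the list add to that count.

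Genes that encode chromatin regulators were among the targets. Of 20 genes for insulator and architectural proteins, 16 were bound (odds ratio 5.40, 1.80 to 16.2, exact adjusted p = 0.00178). The strongest were Cp190, a cofactor shared by several insulator proteins, at 27.1 ± 2.20 times the replicate median (SD, n = 3), and Chro at 16.6 ± 1.21. Next were the shared start of Ibf1 and Ibf2 at 9.19 ± 1.49 and Dref, which encodes the factor that binds the DNA replication-related element, at 6.25 ± 0.200. BEAF-32, CTCF, M1BP, pzg, pita, Trl, ZIPIC, dwg, mod(mdg4), su(Hw) and Clamp were bound at means from 0.573 to 1.94, M1BP in 2 replicates, and Elba1, Elba2, Elba3 and insv had no IDR summit at a TSS. Polycomb and Trithorax group genes were bound at 19 of 24 (odds ratio 5.13, 1.92 to 13.8, exact adjusted p = 7.83e-04). They were led by phol at 23.2 ± 2.36, Scm at 5.98 ± 0.406, trr at 3.65 ± 1.11 and osa at 3.45 ± 0.390. All 5 protein-coding genes of dosage compensation were bound (exact adjusted p = 0.0206). Their values were msl-1 at 22.1 ± 3.65, mof at 9.96 ± 2.13, msl-3 at 2.64 ± 0.155 and msl-2 at 0.967 ± 0.212, and mle, named after its value was seen, at 0.553 ± 0.0257 in the 2 replicates that matched. The long noncoding RNA gene roX1 had an IDR peak of pooled signal 160.6, and roX2 had none. Against genes with any pooled peak at the promoter these calls were lost. Insulator genes were bound at 16 of 17 there, with an odds ratio that was no lower but had a wide interval (6.69, 0.887 to 50.5, exact adjusted p = 0.0514). The odds ratio fell to 1.99 for Polycomb and Trithorax group (0.675 to 5.84, exact adjusted p = 0.341) and to 4.59 for dosage compensation genes (0.254 to 83.1, adjusted p = 0.413). With the 3568 strongest IDR peaks it was 2.93 for insulator, 2.84 for Polycomb and Trithorax group and 9.59 for dosage compensation genes. The dosage compensation call (odds ratio 14.8, 0.820 to 268) was also lost without replicate 1 (7.02, exact adjusted p = 0.0754), without replicate 4 (6.81, adjusted p = 0.0808) and with peaks recovered in all 3 replicates (7.45, adjusted p = 0.0694). Among genes with starts over 1000 bp from others it was lost at a similar odds ratio, with 2 of the 2 genes left bound (15.2, 0.730 to 317, exact adjusted p = 0.111), while insulator (7.61, adjusted p = 0.0308) and Polycomb and Trithorax group genes (7.11, adjusted p = 0.0110) passed. With clusters of starts as units, which neighbours outside the list can make bound, the odds ratio was 8.44 for insulator genes. It was 11.8 for Polycomb and Trithorax group genes, at 21 of 24 clusters.

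Patterning genes and genes of differentiated tissues were bound less often than other genes or missed the threshold. Segmentation genes were bound at 4 of 25 (odds ratio 0.256, 0.0879 to 0.746, exact adjusted p = 0.0117). These were nanos at 2.51 ± 0.423 times the replicate median (SD, n = 3), bcd at 1.01 ± 0.299, hry at 0.646 ± 0.110 and wg at 0.507 ± 0.153. Gut and fat body markers were bound at 1 of 20 (odds ratio 0.0708, exact adjusted p = 7.88e-04), the forkhead gene fkh at 2.32 ± 0.622. The odds ratio of segmentation genes was 0.151 among genes with any pooled peak, and that of gut and fat body markers 0.126 with the 3568 strongest IDR peaks. Both calls were lost among genes with starts over 1000 bp from others, with segmentation genes bound at 3 of 24 (0.433, exact adjusted p = 0.336) and gut and fat body markers at 1 of 15 (0.217, adjusted p = 0.210). Of 8 Hox genes, 1 was bound (odds ratio 0.192, 0.0237 to 1.56, exact adjusted p = 0.173), which was Dfd, named here after its value was seen, with a pooled signal of 154.9 and no replicate holding it among its strongest 7137. Hox genes passed as bound less often with a 250 bp window (0.0969, exact adjusted p = 0.0347), among genes with any pooled peak (0.0694, adjusted p = 0.00755), without replicate 2 (0.0973, adjusted p = 0.0369) and without replicate 4 (0.09996, adjusted p = 0.0438). They did not with a 1000 bp window (exact adjusted p = 0.0911), the 3568 strongest IDR peaks (0.133), peaks recovered in all 3 replicates (0.0698), without peaks beside a stronger summit (0.174), without replicate 1 (0.0745), with clusters of starts as units (0.315) or among genes with starts over 1000 bp from others, where 1 of 7 was bound (odds ratio 0.506, adjusted p = 1). Neuronal markers were bound at 4 of 20 (odds ratio 0.336, 0.112 to 1.01, exact adjusted p = 0.0560), elav at 2.45 ± 0.240, Appl at 0.842 ± 0.183, scrt at 0.560 ± 0.112 and Syx1A at 0.518 ± 0.210. Neuronal markers passed as bound less often with windows of 250 bp (exact adjusted p = 0.00281) and 1000 bp (0.0329), with the 3568 strongest IDR peaks (0.0239), with those recovered in all 3 replicates (0.0277), without those beside a stronger summit (0.0174), without replicate 1 (0.0256) and without replicate 2 (0.0467), at odds ratios from 0.0866 to 0.298. They did not among genes with any pooled peak (0.333, exact adjusted p = 0.193), with clusters of starts as units (0.448, adjusted p = 0.198), without replicate 4 (0.300, adjusted p = 0.0785) or among genes with starts over 1000 bp from others, where 3 of 16 were bound (0.701, adjusted p = 0.861). Muscle markers were bound at 6 of 20 (odds ratio 0.577, exact adjusted p = 0.402). They were led by Tm1 at 2.62 ± 0.459, how at 2.00 ± 0.605, Msp300 at 1.42 ± 0.137 and Mef2 at 1.16 ± 0.205. Muscle markers fell below other genes among those with any pooled peak (odds ratio 0.192, exact adjusted p = 0.00222) and with a 250 bp window (0.291, adjusted p = 0.0440), and missed the threshold in the other 9 settings (exact adjusted p from 0.373 to 0.861). Blood cell markers were bound at 5 of 14 (odds ratio 0.748, exact adjusted p = 0.788). These were drpr at 0.923 ± 0.101, crq at 0.934 ± 0.306 and ush at 0.691 ± 0.245 in 3 replicates, LanB1 at 0.955 in 1 replicate, and LanB2, named after its value was seen, at 0.288 ± 0.0571 in 2 replicates. With the 3568 strongest IDR peaks blood cell markers passed as bound less often (odds ratio 0.0825, exact adjusted p = 0.0241). In the other 10 settings they missed the threshold, at odds ratios from 0.292 to 1.14. Germline markers were bound at 8 of 12 (odds ratio 2.70, exact adjusted p = 0.173). Among them were gcl at 2.01 ± 0.0556, tud at 2.06 ± 0.0699 and piwi at 1.10 ± 0.328 in 2 replicates behind nanos. Heat shock and cognate chaperone genes were bound at 10 of 26 (odds ratio 0.842, exact adjusted p = 0.731). They were led by DnaJ-1 at 21.6 ± 3.18, Hsc70-4 at 9.54 ± 1.12, Hsc70-3 at 8.25 ± 0.849 and Hsp110 at 2.79 ± 0.120. The unbound members include the Hsp70 copies, such as Hsp70Aa and Hsp70Ab, named after the data were seen, where reads may not have been placed. Among genes with any pooled peak, 10 of 14 of this list were bound (odds ratio 1.04). Neither list passed in another setting, with odds ratios from 1.01 to 3.58 for germline markers and from 0.756 to 1.38 for heat shock and cognate chaperone genes.

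Several gene families had few peaks at their starts. Chemoreceptor genes were bound at 5 of 179, 2.79% (exact 95% interval 0.913 to 6.398; odds ratio 0.0379, 0.0156 to 0.0923, adjusted p = 2.46e-34). Among genes with any pooled peak at the promoter they were bound at 5 of 16, 31.25%, with an odds ratio of 0.189 (0.0656 to 0.545, exact adjusted p = 0.00422). With a 1000 bp window the odds ratio was 0.0618, and among genes with starts over 1000 bp from others 0 of 144 were bound (0.0103). These were Gr63a at 1.34 ± 0.151, Ir76a at 0.974 ± 0.131, Ir60e at 0.689 ± 0.148, Ir31a at 0.539 ± 0.175 and Ir60b, named after its value was seen, at 0.566 ± 0.0362 times the replicate median (SD, n = 3). Chorion and yolk protein genes were bound at 0 of 12 (exact upper limit 26.5%, odds ratio 0.0538, adjusted p = 0.00319), a call lost among genes with starts over 1000 bp from others (0.121, adjusted p = 0.0925). None of the 12 had a peak of the pooled relaxed list at its start, so the comparison among genes with any pooled peak could not be made, and with the 3568 strongest IDR peaks the odds ratio was 0.0957. Transfer RNA genes were bound at 24 of 290 (odds ratio 0.122, exact adjusted p = 9.69e-37). The strongest were tRNA:Trp-CCA-2-2 at 4.88 ± 0.299, tRNA:Tyr-GTA-1-8 at 2.92 ± 0.678, tRNA:Ala-TGC-2-1 at 2.56 ± 0.416 and tRNA:Phe-GAA-1-2 at 2.16 ± 0.379. Small nuclear RNA genes were bound at 2 of 32 (odds ratio 0.0898, exact adjusted p = 2.26e-05). These were the U6 genes snRNA:U6:96Ab and snRNA:U6:96Ac under 1 peak at 0.444 ± 0.200, and the odds ratio was 0.0255 to 0.0270 when 1 replicate was left out, 0.0287 with peaks recovered in all 3 replicates and 0.0369 with the 3568 strongest IDR peaks. With windows of 250 and 1000 bp it was 0.0532 and 0.275 for small nuclear RNA genes and 0.0712 and 0.202 for transfer RNA genes, and 0.0768 for the latter with the 3568 strongest IDR peaks. The histone array genes were bound at 0 of 111 (exact adjusted p = 1.19e-26), but these are near-identical copies that also had no peak of the pooled relaxed list, so reads may not have been placed there and the value is uncertain. The same limit may hold for transfer RNA and small nuclear RNA genes, of which 111 of 290 and 13 of 32 had any pooled peak. Among these, 24 of 111 (odds ratio 0.115, 0.0731 to 0.181) and 2 of 13 (0.0759, 0.0168 to 0.343) were bound. With each cluster of starts as 1 unit the differences were smaller. Clusters with transfer RNA genes were bound at 30 of 171 (17.5%, odds ratio 0.359, exact adjusted p = 1.12e-07), those with chemoreceptor genes at 11 of 173 (0.112, adjusted p = 2.73e-20) and those with small nuclear RNA genes at 3 of 26 (0.220, adjusted p = 0.0105).

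**Figure D2:**
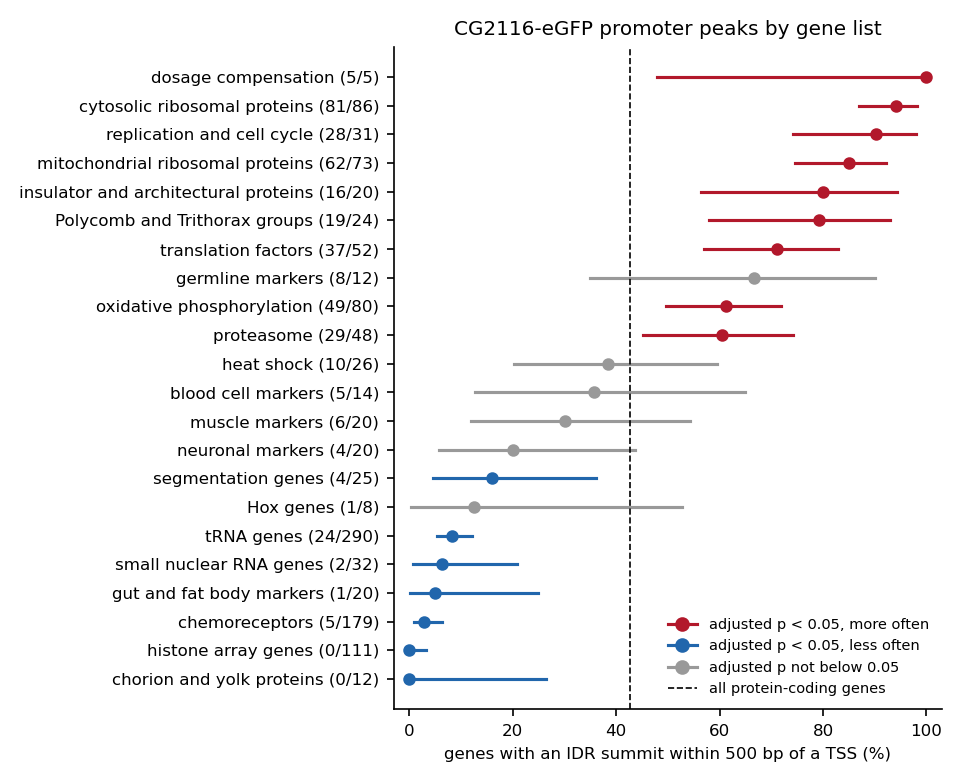
Share of genes in each of 22 lists with an IDR summit within 500 bp of a TSS. Points are percentages with exact 95% binomial intervals, bound and total members stand in brackets, colours give the direction where the Fisher's exact test passed, and the dashed line marks the 42.6% of all protein-coding genes. Cytosolic ribosomal protein genes lie at 94.2% and chemoreceptor genes at 2.79%.

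The sequence under the summits carried elements of housekeeping promoters. TATCGATA, the DNA replication-related element (DRE) recognised by Dref and overlapping the BEAF-32 site, occurred within 100 bp of 895 of 7137 IDR summits, 12.5%, against 0.828% of lower-ranked ones (odds ratio 17.2, 14.6 to 20.3, Fisher's exact p below 1e-300). The odds ratio was 27.9 (21.9 to 35.5) against windows 500 bp away and 28.6 with the 3568 strongest IDR peaks. Its shorter BEAF-32 core CGATA was at 46.6% against 22.4% (3.03, 2.86 to 3.21, and 4.95 with the 3568 strongest IDR peaks). Motif 1, GGTCACACT, bound by M1BP, was at 5.79% against 0.599% (10.2, 8.33 to 12.5, exact adjusted p = 1.42e-139), and its odds ratio was 17.5 (13.01 to 23.5) against windows 500 bp away. Motif 7, CAKCNCTR, was at 18.8% against 6.61% (3.26, 3.01 to 3.54, exact adjusted p = 1.73e-174). Motif 6, GGTATTTT, was at 4.88% against 1.64% (3.08, 2.65 to 3.58, exact adjusted p = 1.52e-45, and 4.79 against windows 500 bp away) and the E-box CAGCTG at 13.5% against 9.17% (1.55, 1.43 to 1.68, adjusted p = 4.64e-24). Motifs of the early activator Zelda, su(Hw), AP-1 and CTCF and the E-box CACGTG missed the threshold, with Fisher's exact adjusted p of 0.150, 0.331, 0.137, 1 and 0.331. Other settings moved 4 of these past it. Zelda was lower within 50 bp (odds ratio 0.542) and against windows 500 bp away (0.458), Zelda (0.658) and su(Hw) (0.809) were lower without replicate 1, and CACGTG with GC matching (1.53) and CTCF with GC matching (1.40) and within 50 bp (1.25) were higher. The GAGA motif (odds ratio 0.815), the TATA box (1.17), the initiator (0.933) and the GATA motif (1.09) passed the test, but their direction turned with another background, so none is given. The GATA motif also missed the threshold without replicate 4 (exact adjusted p = 0.0595), within 50 bp (0.118), with the 3568 strongest IDR peaks (0.436) and with those recovered in all 3 replicates (0.0577), and the TATA box with the 3568 strongest (exact adjusted p = 0.112). IDR summits had a lower GC content, 36.8% ± 7.08 (SD, 7137 summits), than lower-ranked ones, 41.2% ± 8.64 (SD, 21020 summits). With lower-ranked summits drawn to the same GC content, the odds ratio was 15.8 (12.3 to 20.5) for TATCGATA and 8.53 (6.37 to 11.4) for GGTCACACT.

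**Figure D3:**
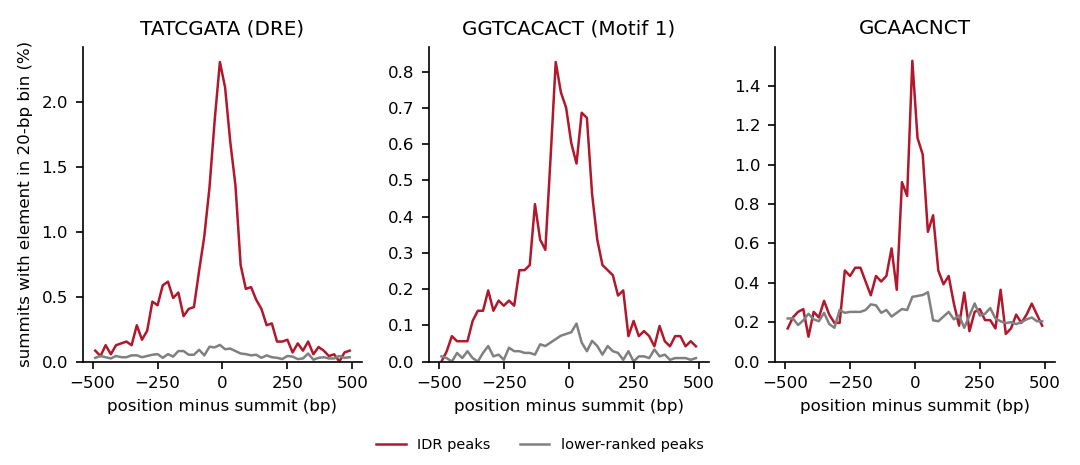
Position of TATCGATA, GGTCACACT and GCAACNCT around peak summits. The horizontal axis is the position minus the summit in genome coordinates (bp), the vertical axis the percentage of summits with the element centred in a 20 bp bin, red for 7137 IDR peaks and grey for 21020 lower-ranked peaks. TATCGATA reaches 2.31% in the bin just below the IDR summits and 0.128% at lower-ranked ones, and is at 0.616% at 200 to 220 bp on the side of lower coordinates against 0.154% on the other.

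A search of all short sequences ranked the DRE first. Of 32896 8-mers, 1007 were more frequent at IDR than at lower-ranked summits on 2L, 2R and 4, and 516 of these passed again on 3L, 3R and X after correction for the number retested. TATCGATA ranked first, with an odds ratio of 14.1 on the first arms and 19.7 (15.8 to 24.5) on the others, followed by its overlapping neighbours ATCGATAG (16.3, 13.2 to 20.1, on the retested arms) and ATCGATAA (9.22, 7.70 to 11.04). GGTCACAC, part of Motif 1, reached 8.62 (6.98 to 10.6) on the retested arms. Among 8-mers without either core, CAACACTG (4.65, 3.67 to 5.90), AACAGCTG (3.22, 2.69 to 3.84), TTTAAAAA (2.29, 2.04 to 2.57), ATTTAAAA (2.25, 2.01 to 2.53) and CAGCCCTG, which matches Motif 7 (7.92, 5.72 to 10.97), came first by p on the first arms. Against GC-matched summits CAACACTG, AACAGCTG and CAGCCCTG stayed among the first 30 8-mers by p. TTTAAAAA and ATTTAAAA, made of A and T alone, did not, so base composition may account for them. With GC-matched lower-ranked summits, 180 8-mers held and TATCGATA again ranked first, with an odds ratio of 20.4 (14.3 to 29.3) on the retested arms. Within 50 bp of the summit 276 held, and against windows 500 bp away 940.

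The elements followed peak strength to different degrees, a view chosen after the data were seen. TATCGATA was within 100 bp of 26.3% of the 714 strongest IDR summits (exact 95% interval 23.1 to 29.7) and of 2.94% of the 713 weakest (1.83 to 4.47). Motif 7 went from 32.4% (28.9 to 35.9) to 9.12% (7.11 to 11.5). Motif 1 was at 5.04% (3.56 to 6.91) in the strongest set, 8.12% (6.23 to 10.4) in the fourth and 3.79% (2.51 to 5.46) in the weakest. GCAACNCT, an element picked after the sequences of the strongest peaks were seen, was at 22.7% (19.7 to 25.9) in the strongest set, 6.16% (4.51 to 8.18) in the second and 3.79% (2.51 to 5.46) in the weakest.

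**Figure D4:**
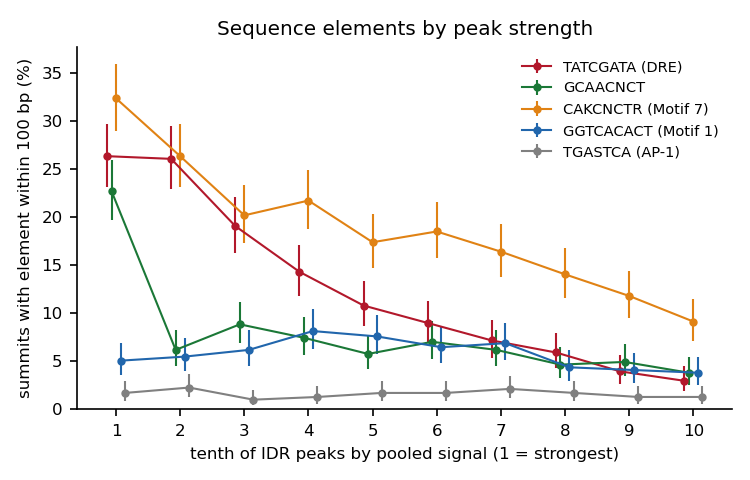
Share of IDR summits with a sequence element within 100 bp, by pooled signal. The 7137 IDR peaks are ordered by signal and split into 10 sets of 713 or 714 (1 is the strongest), points are percentages and bars exact 95% binomial intervals. TATCGATA falls from 26.3% to 2.94% and GCAACNCT is at 22.7% in the strongest set and at most 8.82% in the others.

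At the tagged gene itself, CG2116 (FBgn0030003, X, 8129812 to 8131783, + strand), there were 2 IDR peaks. The peak at its promoter (8129314 to 8129937) had its summit 167 bp upstream of the TSS, at 3.74 ± 1.43 times the replicate median (SD, n = 3), and ranked 487 among 7137. A stronger one (8131565 to 8132451) spanned its 3' end, with the summit 110 bp past the annotated end of the gene and at -392 bp from the TSS of the neighbour CG10958, at 24.9 ± 4.34, and ranked 102. How the fusion gene was inserted, and whether the line holds more copies of this locus than of others, is not given in the sources used here, so these ranks may not be comparable with those of other genes.

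The authors' lists on the older dm3 build held fewer peaks. The IDR list had 6285 peaks on dm3 against 7137 on dm6, a ratio of 1.14 that ran from 1.13 on 3R and X to 1.16 on chromosome 4. The shares per arm were close, with 23.4% on dm3 and 23.2% on dm6 for 3R and 18.4% and 18.2% for X. Positions were not compared between builds.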

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

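On the dm3 build, 9 IDR peaks lay on heterochromatic contigs outside the 6 arms analysed: 4 on 3LHet, 3 on XHet and 2 on 2RHet. They stood out as signal in data outside the comparisons, since the dm6 lists hold peaks on the 6 arms alone. The strongest of them had a pooled signal of 1589. The pooled relaxed list on dm3 has 64 peaks on all contigs outside the 6 arms, unplaced ones included, and replicates 1, 2 and 4 have 70, 59 and 63. No explanation was tested.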

How the results depend on the processing

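Added after seeing the data were the comparison of pairs of replicates and that of feature classes outside promoters, each with its settings, the runs without 1 replicate for features, arms, gene lists, motifs and k-mers, those without IDR peaks beside a stronger summit, and those on GCAACNCT. The promoter odds ratio stayed between 8.66 and 24.6. GCAACNCT kept direction and call in all 10 settings, but it was picked from the strongest peaks that these settings test again. Its stability was thus in large part built in. All 7 feature classes passed in each setting, but as shares of 1 total they follow the promoter share, so this says nothing on the stability of the others. Outside promoters 4 of 6 classes passed, 2 with the stronger N / 2 peaks, 2 with peaks recovered in all 3 replicates, 2 whichever replicate was left out, 4 without peaks beside a stronger summit and 6 against random positions. Of these classes only coding exons kept their call in each of the 7 settings, and intergenic sequence turned from 0.994 to 1.274 with the stronger N / 2 peaks. The share of IDR peaks recovered in all 3 replicates, 64.5%, follows its definition: it was 45.8% at 50 bp, 73.5% at 200 bp, 78.8% by interval overlap, 83.8% with 2 times as many replicate peaks, 34.3% with N / 2, 92.2% for the stronger N / 2 IDR peaks, 68.9% without peaks beside a stronger summit, and 69.7% to 75.4% when 1 replicate was left out and 2 were required. The share of a replicate's strongest summits found among those of another, 74.4% on average, was 58.7% at 50 bp, 82.7% at 200 bp, 87.15% by interval overlap, 60.7% with 2 times as many peaks, 77.6% with N / 2, and 70.5%, 77.1% and 75.6% without replicates 1, 2 and 4. The mean correlation was 0.878 as Pearson's r of log2 signal, and 0.746 to 0.847 without 1 replicate. For arms, 2 of which passed, 1 passed with the stronger N / 2 peaks, 1 with peaks recovered in all 3 replicates, 0 with arm length as background, and 1 to 3 without 1 replicate. Of 22 gene lists 16 passed, and 10 did with genes that have any pooled peak as background, where the chorion and yolk protein and the histone array lists had no members and gave no value. These 10 are not all from the 16, since Hox genes and muscle markers passed only in the second test. Calls were lost there for translation factors, proteasome, oxidative phosphorylation, insulator, Polycomb and Trithorax group, and dosage compensation genes. In place of 279 6-mers, 179 held within 50 bp and 116 with GC-matched background; in place of 516 8-mers, 276 and 180 did, and 940 with windows 500 bp away. CTCF had no direction in the main test (odds ratio 0.999) and passed as higher within 50 bp (1.25) and with GC matching (1.40). Motif directions reversed for the initiator (odds ratio 1.24 against windows 500 bp away), and, with GC matching, GAGA (1.22), the TATA box (0.907) and GATA (0.898). Except where fewer peaks or genes entered, the cause was not tested. Depth is unknown, so weak peaks missing from a replicate are not shown to be absent.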

Other observations

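Chosen only after the data were seen were the element GCAACNCT, the strongest 200 peaks, the search of their 8-mers, the comparison with Motif 7, the sides of the summit on which TATCGATA was counted, the split of TATCGATA by distance to a TSS, and the comparison of replicate 4 with the others. Several forms of the element were looked at before GCAACNCT was taken. In all 5 patterns were tested, and the 3 weighed here were picked after the outcomes were seen; for the other 2, ribosomal protein genes and replicate 4, values are given without weighing. The bounds that would decide each test below were written down before its outcome was seen.

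Many of the strongest CG2116-eGFP sites carried a short sequence, GCAACNCT, that resembles Motif 7, CAKCNCTR, of the 15 motifs fixed in advance. It lay within 100 bp of 76 of the 200 strongest IDR summits, 38.0%, of 6.86% of the other 6937 and of 2.60% of the lower-ranked ones. GCAACNCT was under 14 of the 25 strongest promoter peaks, among them those of Rho1, E(bx), gro, bchs, GlcAT-S, sti and MEP-1, and under the strongest peaks away from promoters, near SIFaR and CG3505, and that near COX7AL2. TATCGATA was under 5 of the 25. Of the 83 copies in the 200 peaks, 46 were centred within 25 bp of the summit and 1 over 75 bp away, and the base after the element was G in 77.1%. A search of all 8-mers, the strongest 200 against the other IDR peaks, called 5 on 2L, 2R and 4, and all 5 passed on 3L, 3R and X: CAACCCTG (odds ratio 14.1, 8.42 to 23.5, on the retested arms), CAACTCTG (9.16), CAGCCCTG (3.68), which matches Motif 7 and not GCAACNCT, AGGGTTGC (13.8) and AGCAACCC (25.3). The element had been noticed on all arms, so the retest is not independent of it. Motif 7 itself lay at 78 of the 200 strongest summits, 39.0%, and at 18.2% of the other IDR summits (odds ratio 2.88, 2.15 to 3.85). Among IDR peaks without Motif 7, GCAACNCT was at 60 of 122 of the strongest and 6.94% of the others (12.97, 8.97 to 18.8).

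For GCAACNCT in the strongest 200 peaks the odds ratio against the other IDR peaks was 8.32 (6.16 to 11.2), 8.32 to 8.92 when a single replicate ranked the peaks, and from 4.50 with the strongest 713 to 22.9 with lower-ranked peaks as background. Base composition alone goes against the 6.94 (4.998 to 9.62) found with IDR peaks of the same GC content, and the make-up of promoters at large against the 7.29 (5.35 to 9.93) among promoter peaks. Those promoter peaks were not matched by class of promoter. Copies of 1 repeated sequence would share flanks, and 0% of the elements (upper limit 4.35%) had the same 10 bp on both sides as an element in another peak. A candidate explanation, as a hypothesis, is that GCAACNCT is a site which the CG2116 protein or a close partner contacts, and it may be a variant of Motif 7. Binding of the protein to GCAACNCT and to a mutated copy in vitro, and ChIP in embryos with the element mutated, would decide it, but the design holds neither, so no biological explanation was tested, and whether other anti-GFP ChIPs give the same strong sites stays open.

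TATCGATA marked many more IDR peaks but graded with strength. GC content does not account for it (odds ratio 15.8, 12.3 to 20.5, with GC matching), nor does lying within 500 bp of a TSS (15.3, 11.5 to 20.4, among such peaks). Over 500 bp from a TSS the odds ratio was 3.63 (2.61 to 5.04). Promoter class and exact distance were not matched, with 4611 of 5166 IDR and 2563 of 3972 lower-ranked promoter summits within 250 bp. A part from the kind of promoter is thus not excluded. Summits could be placed by the TSS, with the element merely nearby. Among IDR peaks over 500 bp from a TSS, TATCGATA was 2.83 times as dense within 50 bp of the summit as at 50 to 96 bp (1.55 to 5.17, 43 against 14 elements), a small count whose lower bound lies just above the 1.5 set as the limit. That set held 51 of the IDR peaks with TATCGATA, against 844 at promoters. Its summits have no TSS of a protein-coding gene within 500 bp, so it cannot decide how summits are placed at promoters. Starts of noncoding genes were not excluded from it. Open chromatin at active promoters bound by Dref or BEAF-32 stays open as a source of these peaks, since no accessibility data were used here.

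TATCGATA reads the same on both strands, yet 150 to 300 bp from IDR summits it lay on the side of lower coordinates 232 times and on the other 104 times (69.0%, 63.8 to 74.0; exact binomial p = 2.32e-12, not adjusted). Without IDR peaks that had a stronger pooled summit within 400 bp on the lower side the share was 47.1% (39.5 to 54.8), without those that had one on either side 47.95% (40.3 to 55.7), and among those with one on the lower side 92.6% (87.4 to 96.1). Since TATCGATA is more frequent at stronger summits, and 900 peaks had such a neighbour on the lower side against 30 on the other, each of these splits also picks the side on which the element is counted, so they decide nothing on its origin. Orientation of genes alone would favour the higher side at − strand genes as much as the lower side at + strand genes. The share was 83.2% where the nearest TSS was on the + strand and 51.7% (43.4 to 59.8) where it was on the − strand. By the bound written down beforehand, the smaller share, 51.7% with its interval of 43.4 to 59.8, could not decide on orientation. The shares at + and − strand genes were not mirror images, which orientation alone would give, but that comparison was not the test set beforehand. Since the shares differ between strands, secondary summits from the authors' peak calling and a part from orientation cannot be told apart here. Among the 7137 strongest peaks of each replicate, 15.7%, 23.2% and 9.05% had a stronger neighbour in replicates 1, 2 and 4.

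Replicate 4 relative to the mean of replicates 1 and 2 had a median log2 ratio of 0.28 at 1697 IDR peaks outside promoters and -0.0036 at 4522 promoter peaks. Across 6219 IDR peaks, Spearman's rho of this ratio was 0.169 with the GC content of the summit and -0.272 with the number of other pooled summits within 600 bp.

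For cytosolic ribosomal protein genes, the odds ratio of being bound was 27.7 (8.40 to 91.4) among genes whose starts lay over 1000 bp from others and 17.1 (4.21 to 69.7) among genes with any pooled peak. For mitochondrial ones it was 3.55 (1.19 to 10.6, exact adjusted p = 0.0511) and 2.89 (1.44 to 5.83).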
